A study of Mus musculus with 204 samples.

How the data were processed

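The series holds 204 single cells from the distal colon of VGLUT2-tdTomato mice. Per the labels' protocols, the muscle layers with the myenteric plexus were dissociated and cultured overnight, and fluorescent cells were pipetted by hand into lysis mix. The library kit gives each well its own i7 barcode and each plate a shared i5 barcode, with no molecular identifiers, so reads and not molecules were counted. Wells of a plate were pooled before amplification.

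The deposited values are log2(RPKM + 1), that is, reads per kilobase of gene and 1000000 reads on a log2 scale, with 1 column per cell and 49492 gene rows. Base 2 and the added 1 were read from the values, since neither is stated. The submitters' processing notes name the mm10 build; the aligner, the counting tool and its strand setting are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart. Columns were matched to cells by the cell number or sequencer index in the labels. The design had been fixed for raw read counts. The deposited table holds RPKM instead, but whole reads can be read back from it, so the planned thresholds in CPM were kept. After undoing the log, each value times gene length and total reads gave a whole number, within a tolerance of 1e-04, for 100% of 2375655 values above 0. Gene lengths were the summed exon lengths of the GENCODE M21 annotation for 31304 genes. For 6331 genes with no matching length, the smallest length that made every value whole was used, and 11857 genes had no reads. The recovered reads of a cell summed to between 0.99979 and 1.00004 times the total implied by its values. On simulated cells sent through the same steps, 100% of 1348414 values were recovered, to the printed precision.

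CPM is recovered reads per 1000000 of their sum. All 204 cells had at least 10000 reads and 1000 genes and were kept. A transcript counted as detected at 10 CPM, and a cell carried a gene list where at least 50% of its measured members were detected. The 26 lists, 14 of cell type markers and 12 of functions, were written before the data were examined and hold 274 genes, of which 273 are in the table. Cells are not replicates, and the labels name no animal or culture, so no test or p-value was computed. Shares have exact Clopper-Pearson 95% intervals, and a share of 0 has the limit that 3 cells give. Plates are the batch in the labels, and values are given within plates. Plates 2 and 3 share 1 series of sequencer indices and a library naming, while plate 1 has its own, so their agreement may be that of 1 set of libraries. Of 6846 pairs of cells within plates, none agreed within sampling noise, with a lowest chi-square per degree of freedom of 5.5 over genes with 10 or more reads in the pair.

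Chat-only and Nos1-only cells were compared by the log2 ratio of mean CPM with a pseudocount of 1, within each plate with at least 5 cells of each class. The ratio understates differences of low genes. On simulated cells of these classes with 33475 genes, the right sign was found on both plates for 92.0% of 50 genes changed by a log2 size of 1 and for 100% of 50 genes at sizes of 2, 3 and 5 each. Unchanged genes had a median absolute log2 ratio of 0.25. Changed and unchanged genes had a mean of at least 20 CPM and, before counting noise, an SD over cells equal to the mean. Real genes could vary more, as Tac1 did, which was detected in 17 of 34 Chat-only cells. For such genes the simulation may overstate how often the sign is found. Named genes are Slc17a6, Slc17a7, Slc17a8, Chat and Nos1, and in each list the 4 members detected in most cells. For the classes they are the 12 genes per direction with the largest smallest-plate ratio. These needed a mean of 20 CPM and detection in 50% of cells of the higher class on each plate, and mitochondrial, ribosomal, Rik and Gm genes were left out. In each list the 2 members with the largest mean ratio of the same sign on both plates were also chosen. Some genes that these rules picked are withheld and not reported here, in the text, the figures or the alternatives. Some members at low CPM, of few cells or with ratios that rest on 1 cell are left unnamed in the text, and further genes of a list were named after their values were seen.

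Clusters were made by the Leiden method (scanpy 1.11.5, igraph 0.11.9, resolution 0.5, 15 neighbours) on 30 principal components of the 2000 most variable genes of log1p(CPM/100), each centred within its plate. No doublet caller was run on so few hand-picked cells. Clusters were named only from the marker lists. Reads misassigned between wells were estimated from 14 genes of which 1 cell held at least 95% of a plate's reads. The median over other cells was 56.7, 85.0 and 34.1 per 1000000 reads of the gene on plates 1, 2 and 3, the last from 1 gene. The first measure for misassigned reads in cells with both Chat and Nos1 was replaced after its result was seen, because the 10 CPM threshold largely fixed it. Coordinates are those of GENCODE M21 on mm10 and span whole protein-coding genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

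Alternatives tried were thresholds of 1 CPM, 50 CPM and any count, a minimum of 1% of the plate's highest count of a gene, cells thinned to 1014523 reads without the 21 that had fewer, other cell filters, equal plate weights and leaving out each plate. For the classes they were pseudocounts of 5 and 0.1, other class rules, a difference of mean logs, trimmed-mean and median-ratio scaling, and no filter on low values. For clusters they were no centring, a resolution of 1.0 and 1000 variable genes. Added after seeing the data were shares among neuronal cells, a threshold of 3 RPKM, classes without cells that carried another type's list, classes without 1 cell at a time, cells with both Chat and Nos1 against Chat-only cells within 1 cluster, clusters without Slc17a6, Chat and Nos1, and 5 other seeds.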

Results

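Single cells picked from the myenteric plexus, the nerve network between the muscle layers of the gut wall, were profiled from the distal colon of VGLUT2-tdTomato mice. In these mice a red fluorescent protein serves as a reporter for Slc17a6, which encodes the vesicular glutamate transporter VGLUT2. Whether it follows present or past expression was not examined. Red cells were picked by hand after dissociation and overnight culture, and each of the 204 samples is the polyadenylated RNA of 1 picked cell. The cells fell on 3 plates, with 66 cells on plate 1, 66 on plate 2 and 72 on plate 3. Reads assigned to genes ranged from 453052 to 14310732 per cell, with medians of 3445516 on plate 1, 4571442 on plate 2 and 4690978 on plate 3. A cell had reads in a median of 12273 genes. The labels name no treatment, animal or culture, so each plate counts as 1 sample without replicates, and no test was made. The 95% intervals below are exact (Clopper-Pearson) and cover counting error only, because cells of a plate may share animals and cultures that the labels do not name.

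The first question was which of the picked cells carried neuronal RNA. All but 52 of the 204 cells carried the pan-neuronal list, meaning that at least 50% of its 13 genes reached 10 CPM (reads per 1000000 reads). That was 74.5% of cells (interval 68.0 to 80.3%), with 81.8% on plate 1, 66.7% on plate 2 and 75% on plate 3. These are called neuronal cells below. In 90 cells all 13 genes were detected, among them Stmn2, a microtubule regulator of growing axons. The other 52 cells had a median of 3 of the 13 genes, at a median depth of 3980277 reads against 4181980 in the neuronal cells. Each of these 52 cells carried at least 1 list of a non-neuronal type, against 56 of the neuronal cells (36.8%).

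Smooth muscle RNA was the most frequent non-neuronal signal. The smooth muscle list, with the contractile genes Acta2, Tagln, Des and Actg2 as its most frequent members, was carried by 75 cells (36.8%, interval 30.1 to 43.8%). Those 75 were 35 of the 52 cells without the neuronal list and 40 cells with it. Tagln was detected in 44.6% of cells, Acta2 in 44.1%, Des in 42.2% and Actg2 in 33.3%. When a transcript also had to exceed 1% of the plate's highest count for that gene, 14.2% of cells carried the smooth muscle list. The endothelial list (Pecam1, Cdh5, Kdr, Cldn5) was carried by 12.3% of cells, with Pecam1 in 21.6%. The fibroblast list was carried by 11.3%, with the collagen gene Col1a1 and the proteoglycan gene Dcn each in 23.0%. The interstitial cell list of Kit and Ano1 was carried by 10.3%, where 1 of its 2 genes was enough, and the glial list by 9.80%, with Sox10 (18.6%), Erbb3 (17.6%) and S100b (14.7%) among its most frequent members. Leukocyte (4.41%), mesothelial (3.43%) and epithelial (2.94%) lists were rarer. Their most frequent members were Csf1r in 23.5%, Krt19 in 8.82% and Krt8 in 11.3% of cells. The list of extrinsic sensory neurons, whose cell bodies lie outside the gut, was carried by 2 cells.

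**Figure D1:**
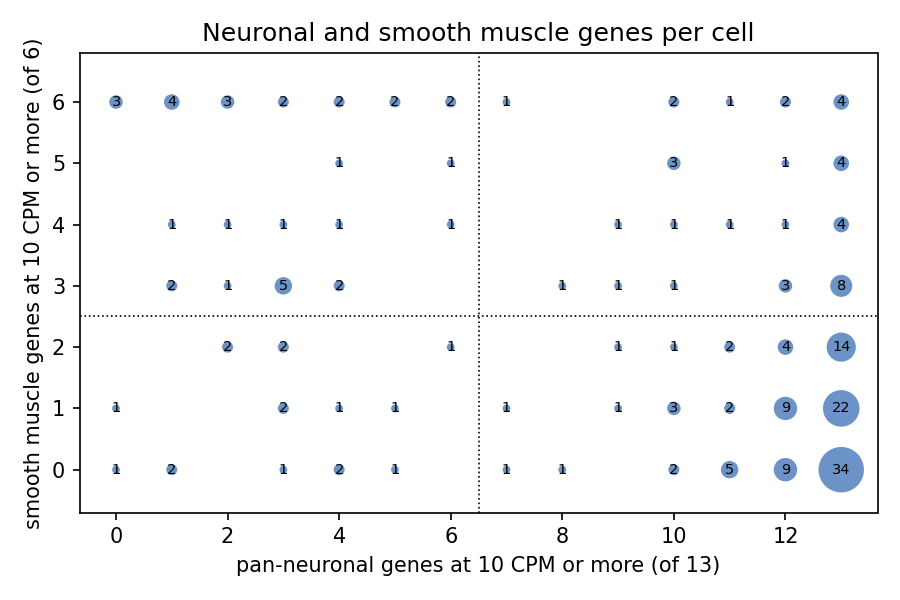
Number of pan-neuronal genes (x axis, of 13) and smooth muscle genes (y axis, of 6) at 10 CPM or more in each of the 204 cells; the area and number of a point give the cells at that position, and dotted lines mark 50% of each list. To the left of the vertical line lie 52 cells, 35 of them above the horizontal line.

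Slc17a6, the gene behind the reporter, was detected at 10 CPM or more in 89 cells (43.6%, interval 36.7 to 50.7%). The share was 66.7% on plate 1, 30.3% on plate 2 and 34.7% on plate 3. All 89 cells carried the pan-neuronal list, so that 58.6% of neuronal cells (interval 50.3 to 66.5%) had Slc17a6. It was found in 0 of the 52 other cells, which allows a share of up to 5.77%. Where detected, its median was 71.5 CPM. The related transporter genes Slc17a7 (VGLUT1) and Slc17a8 (VGLUT3) were detected in 4 cells (1.96%, interval 0.537 to 4.94%) and 2 cells (interval 0.119 to 3.50%). Of the genes that supply glutamate, the glutamine transporters Slc38a2 (88.7%) and Slc38a1 (82.8%) and the glutamine synthetase gene Glul (74.5%) were found in most cells, neuronal or not. In the mm10 build Slc17a6 lies on chromosome 7 from 51622006 to 51671119, Slc17a7 on chromosome 7 from 45163949 to 45176142 and Slc17a8 on chromosome 10 from 89574020 to 89621253.

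Genes for acetylcholine handling were detected in more cells than those for monoamine transmitters. Among the neuronal cells, the acetylcholine-degrading enzyme gene Ache was detected in 88.2%, the vesicular acetylcholine transporter gene Slc18a3 in 77.6%, the choline transporter gene Slc5a7 in 77% and Chat, the acetylcholine-synthesising enzyme gene, in 69.7% (interval 61.8 to 76.9%). In the 52 other cells these shares were between 0 and 5.77%. Of the genes for monoamine transmitters, Dbh was detected in 46.1% of neuronal cells, Ddc in 38.8%, Slc18a2 in 37.5% and Th in 15.1%. Penk, the enkephalin precursor gene, was the most frequent neuropeptide transcript, at 10 CPM or more in 93.4% of neuronal cells and 80.8% of the other cells. Its mean was 5273 CPM, and reads misassigned between wells would add a median of 22.7 CPM per cell, above the detection threshold. Cartpt was detected in 78.3% of neuronal cells, Adcyap1 in 56.6% and Gal in 40.1%. Over all cells Gal was detected in 16.7%, 48.5% and 36.1% on plates 1, 2 and 3. Plates 2 and 3 held the cells with the highest Gal levels, from which misassigned reads can reach other wells. With the count minimum of 1% of the plate's highest, the shares over all cells went from 90.2% to 47.5% for Penk and from 61.8% to 37.3% for Cartpt. Of the intrinsic sensory list, carried by 3 cells, the most frequent members were Cck in 14.2%, Calcb in 10.8%, Vsnl1 in 9.80% and Nog in 7.35% of all cells. The excitatory motor list was carried by 24.0% of all cells, led after Penk by Gfra2 (35.8%), Tac1 (25.0%) and Calb2 (23.0%). The inhibitory motor list was carried by 48.5%, led by Ass1 (84.8%), Cartpt, Etv1 (60.3%) and Nos1 (39.7%). Carrying it does not single out inhibitory cells, since Ass1, Cartpt and Etv1 were detected in 96.7%, 78.3% and 76.3% of neuronal cells.

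Many receptor and channel genes were detected in more of the neuronal cells than of the others. Of 24 glutamate receptor genes, 2 were detected in over 50% of all cells and 11 in under 10%. Grik5, a kainate receptor subunit gene, was found in 86.8% of neuronal cells, the NMDA receptor subunit gene Grin1 in 72.4%, and the AMPA receptor subunit genes Gria2 and Gria4 in 58.6% and 36.2%. The shares in the 52 other cells were 30.8% for Grik5 and 0 for Grin1, Gria2 and Gria4. Nicotinic receptor subunit genes Chrna3 (90.1%), Chrnb2 (84.9%) and Chrnb4 (68.4%) and the muscarinic receptor gene Chrm1 (86.8%) were frequent in neuronal cells. So were the serotonin receptor gene Htr2b (90.1%) and the purinergic receptor genes P2rx4 (66.4%, and 51.9% of the other cells) and P2rx2 (55.3%). Among the most frequent sodium channel genes were Scn9a (84.9% of neuronal cells against 1.92% of the others), Scn3a and Scn3b, and among the most frequent potassium channel genes Kcnq3 (82.2%) and Kcnma1 (73.7%). Calcium and HCN channel genes were led by Cacna1a (80.3%), Cacna1b (77%), Hcn3 (70.4%) and Cacna1c (52.0%). Among 23 mechanosensitive, TRP and acid-sensing channel genes, Trpv2 (88.2%), Tmem63b (83.6%, and 67.3% of the other cells), Tmem63c (71.7%) and Trpc1 (66.4%) were the most frequent in neuronal cells.

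**Figure D2:**
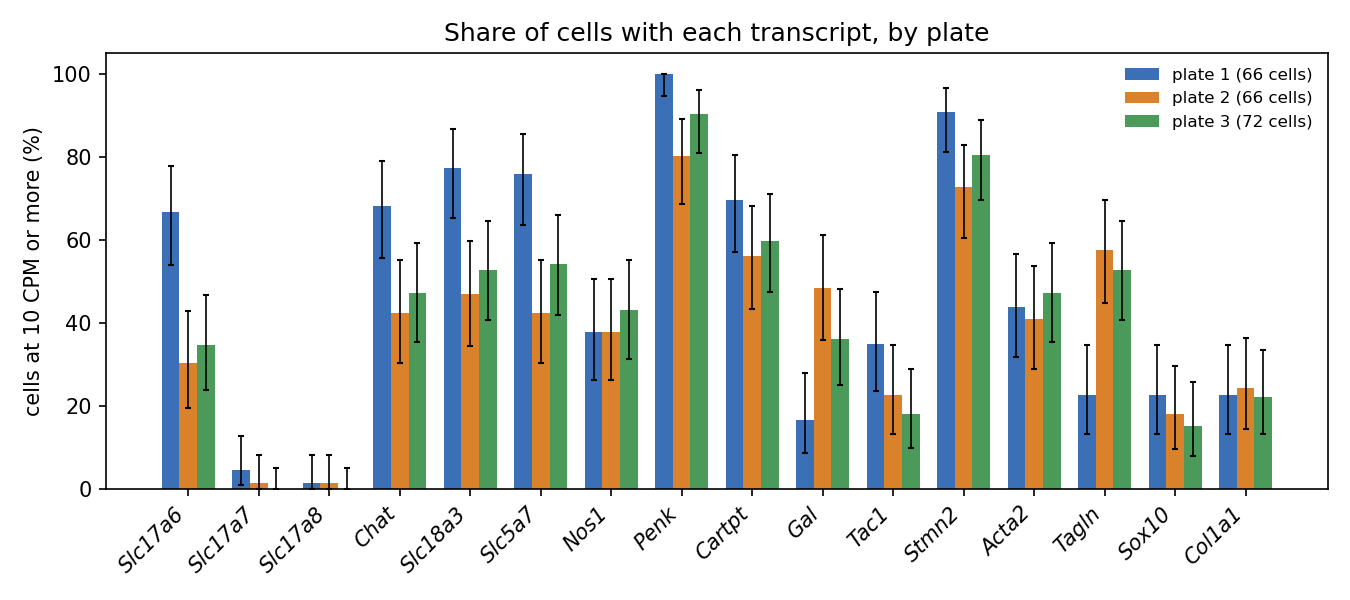
Share of cells (y axis, percent) in which each named transcript (x axis) reached 10 CPM, with 1 bar per plate and exact 95% intervals as error bars. Slc17a6 reached 66.7% on plate 1 and 30.3% and 34.7% on plates 2 and 3.

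Chat and Nos1, the gene of neuronal nitric oxide synthase, mark the main excitatory and inhibitory classes of myenteric neurons, and their overlap was examined next. Chat without Nos1 was found in 57 cells (27.9%, interval 21.9 to 34.6%), Nos1 without Chat in 31 (15.2%, interval 10.6 to 20.9%), both in 50 (24.5%, interval 18.8 to 31.0%) and neither in 66 (32.4%, interval 26.0 to 39.2%). Of the 66 cells with neither transcript, 16 carried the pan-neuronal list. The product of the single shares would give both transcripts in 20.8% of all cells. Within the neuronal cells the share with both was 32.9% against a product of 36.7%, but the plates disagreed, with 40.7% against 38.6% on plate 1, 22.7% against 33.5% on plate 2 and 33.3% against 36.1% on plate 3. Plates differed in the Nos1-only class, which held 3 of 66 cells on plate 1, 15 of 66 on plate 2 and 13 of 72 on plate 3. Nos1 had means of 584.11 and 947.37 CPM in the Nos1-only cells of plates 2 and 3 and of 59.26 and 65.94 CPM in the cells with both. On plate 1 the order was the other way, at 38.93 CPM in the 3 Nos1-only cells and 78.54 CPM in the 22 cells with both. Those 3 cells differed from the class on the other plates, with Gal detected in 0 of them. Cell 40 carried the extrinsic sensory list. Cell 46 had Chat at a log2(CPM + 1) of 2.998, just below the threshold. Cell 23 had 570219 reads, 15.6% of them mitochondrial. The Chat means on plates 1, 2 and 3 were 206.58, 167.45 and 201.54 CPM in Chat-only cells and 167.92, 135.82 and 124.28 CPM in cells with both. At a threshold of 50 CPM the share with both was 11.3%, and at any count it was 61.3%. In mm10 Chat lies on chromosome 14 from 32408203 to 32465989 and Nos1 on chromosome 5 from 117781032 to 117958840.

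Slc17a6 went with Chat. It was detected in 40 of the 57 Chat-only cells (70.2%, interval 56.6 to 81.6%) and 43 of the 50 cells with both (86%, interval 73.3 to 94.2%). In the Nos1-only cells it was detected in 3 of 31 (9.68%, interval 2.04 to 25.8%), of which 2 (cells 40 and 46) were on plate 1. In cells with neither it was detected in 3 of 66 (4.55%). Among neuronal cells Slc17a6 was detected in 83 of 106 with Chat and 6 of 46 without. The same order was found within each plate, with 91.1% against 33.3% on plate 1, 63.0% against 17.6% on plate 2 and 73.5% against 0 on plate 3.

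**Figure D3:**
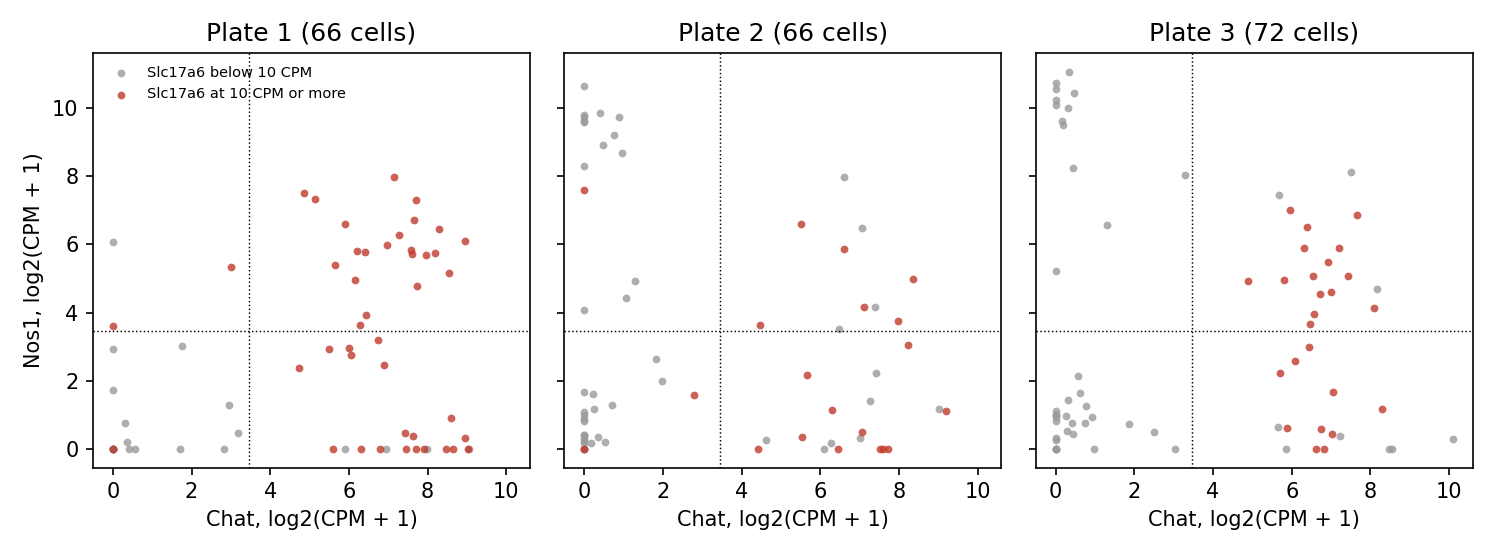
Level of Chat (x axis) and Nos1 (y axis), both as log2(CPM + 1), in each cell of the 3 plates, with red points for cells with Slc17a6 at 10 CPM or more, grey points for the rest and dotted lines at 10 CPM. To the right of the vertical line lie 83 of the 89 cells with Slc17a6.

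Chat-only and Nos1-only cells were compared within plates 2 and 3, since plate 1 had fewer than 5 Nos1-only cells. The comparison held 18 against 15 cells on plate 2 and 16 against 13 on plate 3. By the smaller of the ratios on the 2 plates, Tac1, the substance P precursor gene, differed most towards Chat-only cells, by a log2 ratio of mean CPM of 6.99 on plate 2 and 8.91 on plate 3, and was detected in 17 of 34 Chat-only and 3 of 28 Nos1-only cells. Gal, the galanin gene, differed most in the other direction (-8.43 and -6.83), with means of 6457 and 2830 CPM in Nos1-only cells against 17.8 and 23.8 CPM. The Gal medians in Nos1-only cells were 449.22 and 888.32 CPM, and without the highest cell of each plate (cells 48 and 43 of plates 2 and 3) the ratios were -7.67 and -5.70. Slc17a6 was higher in Chat-only cells on both plates (2.71 and 5.56), at 50.6 and 49.9 CPM against 6.87 and 0.08 CPM. Only 1 of the 15 Nos1-only cells of plate 2 had Slc17a6 at 10 CPM, and without it (cell 33) the ratio there was 5.54. The depth of the Nos1-only cells was not lower, with medians of 5233561 and 6885200 reads against 4211462 and 4986781.

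Besides Tac1, the genes that led towards Chat-only cells were Dmkn (7.06 and 6.36), the olfactory receptor family gene Olfr78 (6.84 and 5.28), Fam19a1 (6.07 and 5.20), Nlrp6, Trerf1, Nell1, Tmem100, Slc18a3 (4.57 and 3.69), Slc5a7 (5.07 and 3.65), Ubash3b and the netrin receptor gene Unc5c (4.58 and 3.37). Besides Gal, those that led towards Nos1-only cells included C1ql1 (-6.68 and -8.46), the vasoactive intestinal peptide gene Vip (-6.38 and -6.27), the inward-rectifier potassium channel gene Kcnj5 (-5.64 and -7.33), Rprml, Bves, the purinergic receptor gene P2ry6 (-4.49 and -7.01), St18, Mfsd4a, the cation channel gene Trpc4 (-3.88 and -5.49) and Popdc3. Some of these means rested on part of the cells. Vip was detected in 16 and Gal in 24 of the 28 Nos1-only cells, against 11 and 12 of the 34 Chat-only cells. The Chat-only detections may partly be misassigned reads. On plate 2 the Gal medians were 8.01, 7.95 and 6.45 CPM in Chat-only cells, cells with both and cells with neither. On plate 1, where the highest Gal level was 47.2 CPM, they were 0. The Vip medians of these classes on plate 3 also lay near 10 CPM, at 8.91, 12.41 and 8.23 CPM. On plate 3 Vip was detected in 53.85% of Nos1-only and 50.0% of Chat-only cells, and without cell 41 the ratio was -4.99. Leaving out 1 cell moved the ratio on a plate by over 1.5 times for 20 of 23 genes named by size and reversed or removed the difference for 0 of them. Among the genes chosen from lists it moved 33 of 35 and reversed or removed the difference on a plate for 13. Of the excitatory motor list, Gfra2, a neurturin receptor gene, was higher in Chat-only cells (6.52 and 6.06).

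**Figure D4:**
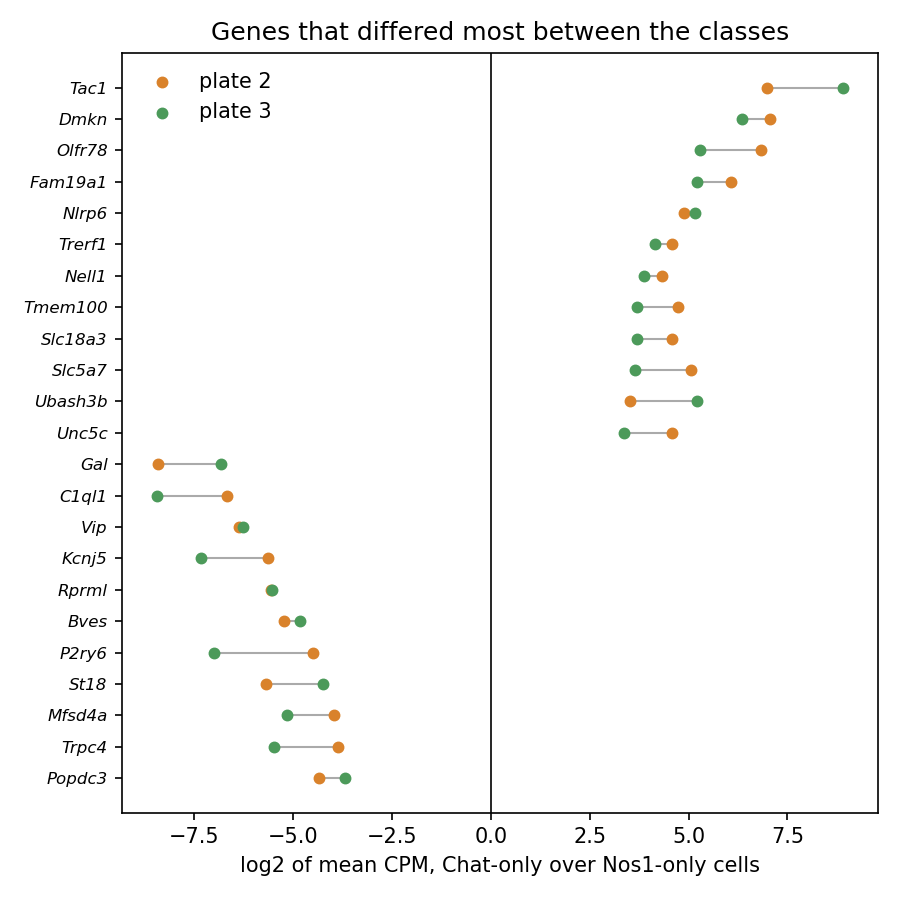
Log2 ratio of mean CPM in Chat-only over Nos1-only cells (x axis) for genes named by size in each direction, with an orange point for plate 2, a green point for plate 3 and a grey line between them. Tac1 lies at 6.99 and 8.91 and Gal at -8.43 and -6.83.

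Receptor and channel genes differed between the classes in both directions. Higher in mean CPM in Chat-only cells on both plates were the metabotropic glutamate receptor gene Grm7 (3.65 and 2.61), P2ry1 (4.00 and 3.45), the calcium-activated potassium channel gene Kcnn3 (2.49 and 2.68), Kcnj6 (1.06 and 2.01) and the sodium channel gene Scn3b (3.12 and 1.67). Grm7 was detected on plate 3 in a smaller share of Chat-only (37.5%) than of Nos1-only cells (53.85%). Higher in Nos1-only cells were the acid-sensing channel gene Asic2 (-2.25 and -3.25), the muscarinic receptor gene Chrm2 (-0.79 and -2.49, the first -1.61 without cell 19) and the calcium channel gene Cacna1d (-1.82 and -1.77). Chrna7 had 0 reads in Chat-only cells and means of 7.19 and 7.38 CPM in Nos1-only cells, where it was detected in 6 of 28. The neurofilament genes Nefm (2.77 and 1.18) and Nefl (2.14 and 0.89) and the injury-linked gene Sox11 (2.01 and 1.83) had higher means in Chat-only cells. Nefm and Nefl were nevertheless detected in a smaller share of Chat-only cells on both plates, in all in 29 and 22 of 34 against 27 and 24 of 28. RNA of other cell types was compared as well, and the plates disagreed on smooth muscle. The smooth muscle list was carried by 6 of 18 Chat-only and 6 of 15 Nos1-only cells on plate 2, and by 5 of 16 against 1 of 13 on plate 3. The ratio of Tagln was 0.87 on plate 2, or -2.18 without cell 2, and 5.39 on plate 3, or 3.21 without cell 14. The fibroblast list was carried by 3 and 2 Chat-only cells and by 0 Nos1-only cells, with Col1a2 at 2.34 and 4.36, or 1.33 and 3.44 without cells 2 and 14. In cells with the neuronal list and no list of another type, the mean log2 ratio was 5.16 for Slc17a6, 8.39 for Tac1 and -8.21 for Gal. When classes were set by a ratio of at least 4 between Chat and Nos1, which took 80 and 34 cells and brought in plate 1, the log2 ratio of Gal was -4.78.

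Unsupervised clustering with plate means removed gave 5 clusters, and 6 with 3 of 5 other random seeds. Cluster 0 (79 cells, 38.7%, interval 32.0 to 45.8%) was smooth muscle-like, with Fn1, Tagln, Cnn1, Des and Clcf1 as leading genes. It held 53 cells that carried the smooth muscle list and 27 with the neuronal list, and glial, fibroblast and endothelial lists were carried by 19, 20 and 18 of its cells. Cluster 2 (22 cells, 10.8%) was excitatory motor-like, led by Cldn11, Ffar3, Nfatc1, Lamc3 and Tac1. Cluster 4 (24 cells, 11.8%) was inhibitory motor-like, with Gal, Rprml, C1ql1 and Popdc3 among its leading genes, and held 12 cells from plate 2, 10 from plate 3 and 2 from plate 1, which are the 2 cells that carried the list of extrinsic sensory neurons. Cluster 1 (57 cells, 27.9%) was led by Islr2, Tbx3os2, Rnf183, Bdnf and Mfap3l and stayed unnamed. Cluster 3 (22 cells) was led by Cym, Topaz1, Aox2, Ttll10 and Zan, had a median of 1672832 reads and 10.0% mitochondrial reads, and also stayed unnamed. The inhibitory motor list was carried by 19 of 24 cells of cluster 4, but also by 47 of 57 of cluster 1 and 21 of 22 of cluster 3. The name of cluster 4 therefore rests on the list members Gal and Ass1 among its leading genes. With Slc17a6, Chat and Nos1 left out of the clustering, Slc17a6 was detected in 86% of the 57 cells matching cluster 1 (interval 74.2 to 93.7%), 63.6% of the 22 matching cluster 2, 58.3% of the 24 matching cluster 3, 14.3% of the 77 matching cluster 0 and 4.17% of the 24 matching cluster 4 (interval 0.105 to 21.1%). The 1 cell with Slc17a6 in cluster 4 was cell 40 of plate 1, 1 of the 2 with the extrinsic sensory list. The smooth muscle-like cluster depended on the random seed, with 24.0% of cells at the lowest of 5 other seeds.

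The list of genes linked to nerve injury and culture was carried by most cells. All cells had been cultured, so no effect of injury or culture can be read from these levels. The 10 genes of this list had a mean log2(CPM + 1) of 5.53 (SD over cells 1.65), with 6.10 on plate 1, 5.20 on plate 2 and 5.32 on plate 3, and 171 cells (83.8%) carried the list. It was carried by 96.7% of neuronal cells and 46.2% of the others, with list means of 6.18 and 3.64. Jun was detected in 92.6% of cells, Klf6 in 92.2%, Gadd45g in 88.2% and Gap43, a growth cone gene, in 82.4%. The injury transcription factor gene Atf3 was detected in 74% (interval 67.4 to 79.9%). Gap43, Stmn4 and Sox11 had means of 9.02, 8.65 and 4.61 in neuronal cells against 3.20, 1.68 and 0.35 in the others. Atf3 differed less (5.63 against 5.14), and Klf6 (6.92 against 7.59) and Gadd45a (4.33 against 4.80) were higher in the others. Of the immediate early genes, which respond quickly to cell stimulation, Junb was detected in 93.6%, Dusp1 in 89.2%, Ier2 in 82.8%, Egr1 in 61.8% and Fos in 43.1% of cells. Arc (13.2%) and Npas4 (4.41%) were less frequent. The list mean was 3.75 in neuronal cells and 3.81 in the other cells, and 46.1% of all cells carried the list, from 63.6% on plate 1 to 26.4% on plate 3.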

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

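The alternatives among neuronal cells, at 3 RPKM, without cells of another type, without 1 cell at a time and with other seeds were chosen after seeing the data. No paired analysis was possible because the numbers only name cells and no test was made. The share of cells with Slc17a6, Chat, Nos1 and both Chat and Nos1 was 52.0%, 60.3%, 57.4% and 38.2% at 1 CPM, 31.9%, 45.1%, 25.5% and 11.3% at 50 CPM, and 60.3%, 76%, 77.9% and 61.3% at any count. Among neuronal cells the shares were 58.6%, 69.7%, 52.6% and 32.9%. At 3 RPKM Nos1 was found in 27.9% and both in 15.2%. With the minimum of 1% of the highest count, Nos1 was found in 32.4% and both in 19.1%. The pan-neuronal list was carried by 99.5% of cells at 1 CPM and 100% at any count, so it separates cells only at higher thresholds. The smooth muscle list was carried by 79.9% at 1 CPM, 19.1% at 50 CPM, 97.1% at any count, 14.2% with the 1% minimum and 26.3% among neuronal cells. Higher thresholds lower every share by construction.

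Leaving out each plate gave 32.6 to 50.0% for Slc17a6, 44.9 to 57.2% for Chat, 37.9 to 40.6% for Nos1, 20.3 to 29.0% for both, 71.0 to 78.3% for the pan-neuronal and 33.3 to 41.3% for the smooth muscle list. The lowest Slc17a6 share was that without plate 1. In the same runs the log2 ratio went from 2.71 to 5.56 for Slc17a6, 6.99 to 8.91 for Tac1 and -8.43 to -6.83 for Gal, where leaving out plate 1 moved nothing because it was not used. The injury list mean went from 5.26 to 5.70 and the immediate early list mean from 3.56 to 4.04.

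With a difference of mean logs the ratio was 3.86 for Tac1 and -5.50 for Gal, and with classes by ratio -4.78 for Gal. All 24 genes named by size for the classes kept their sign under each of the 16 alternatives, which is likely for genes chosen by large ratios. Of them 2 were again among the 12 per direction with classes by ratio, 11 with a difference of mean logs, 12 without cells of another type, 13 and 14 at class thresholds of 1 and 50 CPM, 13 with no low-value filter, 15 after thinning, and 14 and 13 without plates 2 and 3. Among the ratios that changed sign were those of Tph2 (0.31 at 1 CPM, 0.28 at 50 CPM, 0.56 thinned), Nr4a1 (0.85 at 50 CPM), Cdh5 (-0.99 with classes by ratio), and Cacna1g (0.11) and Lum (-0.06) without cells of another type; the cause was not tested. Resolution 1.0 gave 8 clusters, and seeds 1, 2 and 5, 1000 variable genes and no centring gave 6 each. The smooth muscle-like cluster held 15.2% of cells at that resolution, 30.4% without centring, 29.9% with 1000 genes, and 30.4%, 31.4% and 24.0% with seeds 1, 2 and 5. The filters on reads and genes removed no cell, so they say nothing about stability. Leaving out the 7 cells over 25% mitochondrial reads changed the share with Slc17a6 from 43.6% to 44.7%. The share went from 52.5% to 53.3% for Chat, 39.7% to 40.6% for Nos1 and 36.8% to 34.5% for the smooth muscle list. No share left its exact interval of the main result. Thinning to 1014523 reads, which left out the 21 shallowest cells, took 1 of the other shares out of its interval. Of the 55 other class ratios thinning reversed 1 and changed 14 by more than the gene's SD over plates 2 and 3.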

Other observations

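The comparison of cells with both Chat and Nos1 against Chat-only cells, the search for single cells with rare transcripts, and all tests below except that at equal depth were chosen after the results were seen. Cells with both transcripts had more RNA of the serotonin receptor gene Htr3a than Chat-only cells in each plate, with log2 ratios of mean CPM of 3.56, 4.42 and 2.68 on plates 1, 2 and 3 (22 against 23, 10 against 18 and 18 against 16 cells). Htr3a was detected in 28 of the 50 cells with both and 10 of the 57 Chat-only cells, and the ratios were 4.39, 6.36 and 3.83 without Chat-only cells 49, 22 and 27. Dbh (2.28, 3.86 and 2.65) and Ddc (3.04, 2.36 and 2.42), genes of monoamine synthesis, followed, with Dbh in 40 of 50 against 20 of 57 cells. Without 1 cell Dbh was at 2.86 on plate 1 (cell 54) and 5.00 on plate 2 (cell 34), and Ddc at 1.45 on plate 2 (cell 23). Klhl1, Ntng1, Lrrc4c, Pcp4 and Itm2a were also higher in cells with both. Tac1 was lower in them (-3.08, -8.18 and -2.12), as were Dmkn, Pdpn, Pcsk2, Col27a1 and Utrn. On plate 3 Tac1 was detected in 1 of the 18 cells with both, and without that cell (62) the ratio was -8.69; on plate 1 it was -5.51 without cell 21. Leaving out 1 cell moved the ratio on a plate by over 1.5 times for 16 of the 24 genes chosen in this comparison and changed the sign of 0. The 2 classes also differed in their clusters. Of the 50 cells with both, 35 were in cluster 1 and 11 in cluster 3, while of the 57 Chat-only cells 20 were in the excitatory motor-like cluster 2, 17 in cluster 1 and 14 in the smooth muscle-like cluster 0. Within cluster 1, with 35 cells with both and 17 Chat-only cells, Htr3a stayed higher in cells with both (2.09, 4.90 and 4.05). Ddc stayed higher on plates 1 and 3 (1.90 and 2.11) but hardly differed on plate 2 (0.24). Lrrc4c and Pcp4 were also higher on each plate, Pcp4 by little on plates 1 and 2 (0.31 and 0.14). Dbh (-0.14, 2.21 and 3.74) was not higher on plate 1, nor were Klhl1 (-0.21), Ntng1 (-0.04) and Itm2a (-0.08). No gene named as lower kept 1 direction, among them Tac1 (1.26, -1.45 and -2.13) and Utrn (-0.17, 2.41 and 0.40). Most of the differences thus did not hold within cluster 1 and may follow the clusters, which were made from the same cells.

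A few single cells held nearly all reads of a gene in their plate. On plate 1, cell 40 had 97.5% of the Calca reads, at 30343 CPM, and Slc17a6 at 85.3 CPM, and it carried the extrinsic sensory list. Cell 43 of the same plate had 96.6% of the reads of Fxyd2 and carried that list too. On plate 2, cell 22 had 99.1% of the Sst reads and the neuronal list, and cell 3 had 98.6% of the Cd74 reads and the leukocyte list. Cell 14 of plate 2 had 99.2% of the reads of Pbsn and 98.1% of those of Tgm4, which encode secretory proteins of the prostate, with Krt8, Krt18 and Epcam at 10039, 11745 and 2270 CPM. It had 5 of 13 pan-neuronal genes.

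The 50 cells with both Chat and Nos1 were weighed against technical sources. Reads misassigned at the 95th percentile of the rate would give these cells a median of 3.095 CPM of Chat and 2.391 CPM of Nos1. The cells were chosen at 10 CPM, which is a median of 3.2 and 4.2 times these levels. Their own levels were a median of 39.7 and 23.0 times them, and at the lowest 2.04 and 1.03 times. Pooled over the plates, these medians argue against misassigned reads for most of the cells. Single plates stay open, because the multiples are pooled and the rate of plate 3 rests on 1 gene. Median Nos1 in the cells with both was 55.66, 23.83 and 32.7 CPM on plates 1, 2 and 3. With the count minimum of 1% of the plate's highest, the share of cells with both went from 24.5% to 19.1%. A Chat-only and a Nos1-only cell in 1 well would dilute the 12 genes named for Nos1-only cells as Nos1 is diluted. On plates 2 and 3 Nos1 was at a log2 ratio of -3.55 to the Nos1-only cells and those genes at a median of -5.43, a difference of -1.88, with 10 of 12 genes more than 1 below Nos1. The 12 genes were chosen on the same Nos1-only cells. The 22 cells with both on plate 1 were not tested in this way, because that plate had only 3 Nos1-only cells. Pairs of other cells stay open, and no biological explanation was tested.

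In all but 89 of the 204 cells picked for the VGLUT2 reporter, Slc17a6 was below 10 CPM. Of those cells 52 did not carry the pan-neuronal list, which does not show whether they were other cells or damaged neurons. Picked cells that are not neurons cannot be the whole cause, since 41.4% of the neuronal cells (interval 33.5 to 49.7%) also lacked Slc17a6. Too few reads would affect neuronal cells with and without Chat alike, yet Slc17a6 was found in 13.0% of those without Chat against 78.3% of those with it, at median depths of 4179216 and 4181980 reads. Poor capture of RNA could lose Chat and Slc17a6 together, so this does not decide for cells with neither Chat nor Nos1. That class held 16 neuronal cells, of which cells 2, 6, 23, 28, 42 and 71 of plate 3 had reads in 3883 to 5716 genes. The rest of the 16 had reads in 6829 to 14274 genes, with cells 31, 39, 51 and 58 of plate 1 at 13729, 14172, 14274 and 14117. Few detected genes thus describe only part of the class. The median of all neuronal cells was 12713.5 genes. Of the 63 neuronal cells without Slc17a6, 41 had 0 of its reads. Reporter signal that outlasts the transcript, and transcript lost in culture, could apply and were not tested.

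Nos1-only cells made up 4.55% of plate 1 and 20.3% of plates 2 and 3 together. With cells thinned to the same depth, which left out the 21 shallowest cells, the shares were 1.61% (interval 0.0410 to 8.66%) and 19.8% (13.1 to 28.1%), which argues against the lower depth of plate 1. Plate 1 did not have fewer neuronal cells, at 81.8% against 66.7% and 75% on plates 2 and 3. Among neuronal cells the Nos1-only shares were 5.56% (1.16 to 15.4%) and 27.6% (19.0 to 37.5%), so the difference remained. The highest Gal level on plate 1 was 47.2 CPM, against 43581 and 21305 CPM on the others. A difference in animals, gut position, picking or library batch cannot be told apart, because each plate is 1 sample and plates 2 and 3 share a sequencer index series and library naming that plate 1 does not.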
